A study of Rattus norvegicus with 4 samples.

How the data were processed

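RNA sequencing libraries of rat OPC soma (n = 2) and protrusions (n = 2), collected after 24 h on a transwell membrane, were compared. Groups and replicate numbers came from the sample titles. Per the labels' protocols the RNA was enriched for mRNA and libraries were made with a directional kit, and each library was a pool of RNA from several experiments. The labels do not say that the pools were made of separate cultures, so p-values measure only the spread between these libraries, which may be technical.

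The authors deposited 1 table of linear FPKM values with 22509 gene rows, each with a symbol, an Ensembl identifier, a description and a gene span on Rnor_5.0. Per the submitters' processing notes, reads were aligned with TopHat to Rnor_5.0. The version of the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping antisense genes may not be told apart. All 4 value columns were matched to samples by title.

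FPKM are scaled to gene length and library total, so a gene falls when other genes take more of a library. The low values fell on steps, which allowed whole reads to be recovered. Library totals were taken from the steps of genes whose span is at most 1200 bp and equals their exon length, and for each gene the shortest exon length of at least 30 bp was sought that made the values of all libraries whole read numbers within a relative tolerance of 2e-07. This gave whole reads for 19206 of 19207 genes above 0, or 99.99%. On reads simulated with the recovered lengths taken as true, the same length was found for 96.5% of 11819 genes and that length or a divisor of it for 100%. The simulation could therefore not show whether lengths recovered from the real data were themselves divisors of the exon lengths. The totals were 86827042 (soma 1), 79637207 (soma 2), 52428192 (protrusion 1) and 73623467 (protrusion 2). Intervals on recovered reads are exact 95% intervals of a rate ratio conditional on the sum, a group at 0 was set to a floor of 3 reads over its libraries, and both cover counting error only, since PCR copies are not independent molecules.

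The 11812 genes with a mean of at least 1 FPKM over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), without further scaling, with an intensity-dependent prior variance (eBayes with a trend), two-sided, and Benjamini-Hochberg adjustment over all tested genes with a threshold of 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes, while folds are ratios of mean FPKM. With n = 2 the spread of each gene borrows from the others. On simulated reads for 11748 genes with a coefficient of variation of 10%, the test called 58.2% of 67 genes changed 1.5-fold. It called 100% of 64 changed 2-fold and 100% of 63 changed 4-fold, and 18 unchanged genes were called. The simulation held no shift of most genes, and some real genes vary more, such as Mbp at 237 and 1163 FPKM in soma. These shares therefore do not measure power or error in the real data.

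The 25 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were matched by symbol, then by Ensembl identifier, then by older or newer symbols from a RefSeq table of another assembly (GRCr8), which was used for names only. Of 79 ribosomal protein symbols 77 matched, of 90 oxidative phosphorylation symbols 75, and of 24 OPC markers 23. Where a symbol stood on several rows (400 symbols on 852 rows) the row with the highest mean was used. Genes with near-identical copies, such as ribosomal protein and haemoglobin genes, are uncertain, because how reads matching several copies were counted is not stated. Malat1 was not matched. Lists share members: Kif1c, Trak2 and Dynll2 stand in both the fibroblast protrusion and the motor list, and Net1 in both the former and the Rho list.

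Lists with at least 3 tested members, 23 of the 25, were tested with limma's camera, a competitive test against all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. With the correlation estimated per list none of the 12 camera calls held, and 2 lists had an unadjusted p under 0.05. In that form camera uses the 2 residual degrees of freedom of the fit, which leaves it little power. The estimates for the fibroblast protrusion (-0.037), neuron (-0.029) and blood cell lists (-0.477) lay below the preset value, so correlation did not end those calls. The fry test, which asks whether a list moves on balance away from 0, called the fibroblast protrusion and the blood cell lists. The genes named were the 10 with the largest log2 change in each direction among those that passed, with a mean of at least 5 FPKM and both protrusion libraries beyond both soma libraries, leaving out symbols that are only database identifiers. Of each list up to 3 passing members with the largest change at a mean of at least 5 FPKM were added, or the 2 most abundant where none passed, and Jmy, Actb, Mbp, Pdgfra, Cspg4, Sox10, Olig2, Gfap, Tubb3 and Rab13 in any case. Not all list members taken by the rule are described. Database identifiers made up 194 of the higher and 386 of the lower genes.

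Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, median-of-ratios scaling (factors 1.26, 1.30, 0.724 and 0.844 for soma 1, soma 2, protrusion 1 and protrusion 2), quantile normalization, rescaling to the sum outside ribosomal protein and mitochondrial genes, a robust prior, no trend, a test against a 1.5-fold minimum change, the replicate number as a block, and leaving out each library. Added after seeing the data were limma voom on the recovered reads, removal of the trend with exon length by loess, rescaling without rDNA-like loci (7 rows picked by protein descriptions, of which 1 names an rRNA promoter binding protein), rescaling to the summed FPKM of all genes, and fry after median-of-ratios scaling. Leaving out a library leaves 1 in its fraction, which is assumed to vary like the other fraction. Such a fit has 1 residual degree of freedom. Without soma 1 or soma 2 the limma prior was infinite, so each gene's own spread was ignored. Calls gained or lost with a library left out may therefore come from the fit rather than from that library.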

Results

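Oligodendrocyte precursor cells (OPCs), the glial progenitors that give rise to myelinating oligodendrocytes, were purified from cortical cultures of newborn Wistar rats. They were kept for 24 h on a porous membrane with a growth factor and laminin gradient, which let extensions through the pores and held the cell bodies back. RNA scraped from the upper face (soma) and RNA lysed from the lower face (protrusions) was enriched for mRNA and sequenced. The series held 2 soma and 2 protrusion libraries, and because protrusions gave little RNA each library pooled RNA of several experiments. The totals behind the FPKM values came to 86827042 reads in soma 1, 79637207 in soma 2, 52428192 in protrusion 1 and 73623467 in protrusion 2. Of 22509 annotated genes, 11812 had a mean of at least 1 FPKM and were tested, with a median of 1399 recovered reads per library. Across those genes, which are not independent replicates, Pearson's r of the log2 values was 0.973 between the soma libraries, 0.989 between the protrusion libraries and 0.914 to 0.935 between fractions.

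The comparison asked which transcripts were enriched in newly formed protrusions relative to the cell body. The transcript of Lpar1, a lysophosphatidic acid receptor, was 15.0-fold higher in protrusions, at 298 ± 11.0 FPKM against 19.9 ± 10.0 in soma (SD, n = 2 each), and 23.4-fold without soma 2. Nes, which encodes the intermediate filament nestin, was 13.6-fold higher at 322 ± 36.1 against 23.7 ± 1.66 FPKM. Kif1c, a kinesin motor, was 11.7-fold higher at 492 ± 2.20 against 41.9 ± 0.99 FPKM. Sh3pxd2a, a scaffold protein of podosomes and invadopodia, was 11.6-fold higher at 553 ± 35.5 against 47.7 ± 15.0 FPKM. The other 6 genes with the largest rises were Nefm (neurofilament medium chain), Cenpb (a centromere protein), Pkp4 (plakophilin 4), Mbp (myelin basic protein), Trak2 (a kinesin adaptor) and Gdf11 (a TGF-beta family ligand), at 7.79-fold to 11.4-fold. Without soma 2 Nefm was 21.5-fold and Mbp 23.0-fold higher, and without soma 1 Mbp was 4.69-fold higher. In the limma fit the log2 changes of these 10 genes ran from 3.35 to 3.93, with adjusted p from 4.78e-06 for Nes to 0.00138 for Mbp. In Rnor_5.0 coordinates Lpar1 lies on chromosome 5 from 79707135 to 79824358, Nes on chromosome 2 from 206747073 to 206755585, Kif1c on chromosome 10 from 57067764 to 57097459 and Mbp on chromosome 18 from 78473296 to 78504226.

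The 10 genes with the largest falls moved less, with log2 changes from -2.12 to -1.86. They were Leprel2 (a collagen prolyl hydroxylase), Adm (adrenomedullin), Vegfa (a vascular growth factor), Dhcr7 and Msmo1 (enzymes of cholesterol synthesis), F3 (tissue factor), Leng8, Troap (a spindle protein), Irf3 (an interferon regulatory factor) and Ccnl2 (cyclin L2). Leprel2 was at 8.50 ± 1.07 FPKM in protrusions and 40.0 ± 0.89 in soma, with an adjusted p of 5.6e-05. Vegfa was at 12.5 ± 4.38 and 54.6 ± 16.8 FPKM, with an adjusted p of 0.000625. All 10 were also lower after median-of-ratios scaling, where Leprel2 was at -1.45 and Ccnl2 at -1.20 on the log2 scale. Under quantile normalization Troap no longer passed, with an adjusted p of 0.0514.

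With the deposited scaling, limma called 854 of the 11812 tested genes higher and 6817 lower in protrusions at a Benjamini-Hochberg adjusted p under 0.05. Of these calls 88.9% were lower. The median log2 change of all tested genes was -0.61, and changes are to be read relative to it. Counts of falls in the gene lists below are likewise to be read against the 6817 of 11812. Median-of-ratios scaling moved that median to -0.02 and gave 1922 higher and 605 lower genes (23.9% lower), and quantile normalization gave 1284 and 990 (43.5% lower). Under both the deposited and the median-of-ratios scaling, 847 genes were higher and 605 were lower, and 366 and 38 of these moved at least 2-fold each time. Median-of-ratios scaling raised most log2 changes, so 847 of the 854 rises passed again, which is no second test of a rise. For falls it was the stricter scaling. A few genes took more of the protrusion libraries: the 20 most abundant held 31.2% and 20.1% of the summed FPKM in protrusions 1 and 2, against 11.3% and 9.80% in soma 1 and 2. Among them were loci of a group of 7 called rDNA-like here, chosen by their descriptions after their values were seen and not checked against a genome, which held 22.1% and 10.1% of the summed FPKM in the protrusion libraries and 5.44% and 2.97% in the soma libraries. The median log2 change was -0.52 without protrusion 1, -0.69 without protrusion 2, -0.61 without soma 1 and -0.59 without soma 2. Fewer genes passed without a protrusion library than without a soma library, but the variance prior also differed between these fits.

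**Figure D1:**
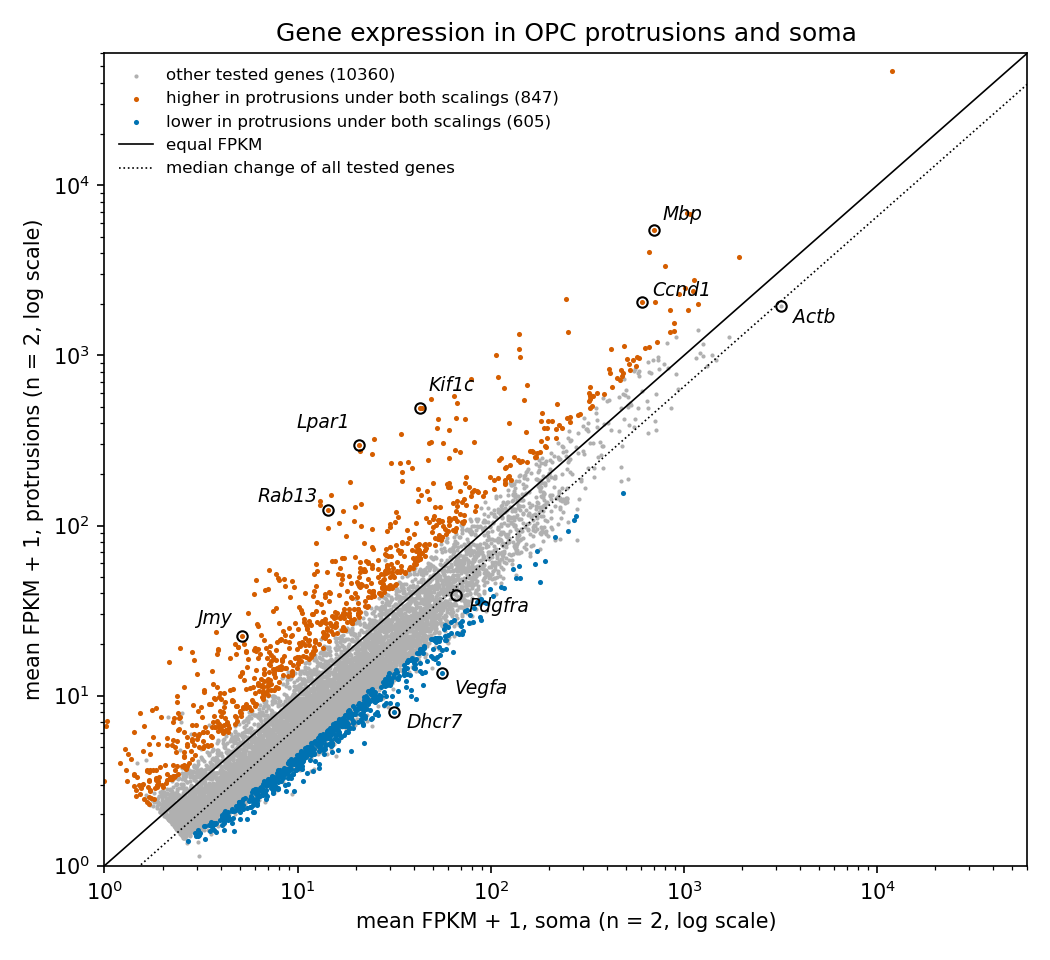
Mean FPKM + 1 of each tested gene in soma (x axis) and protrusions (y axis), both on log scales, n = 2 libraries each; orange and blue points are the 847 higher and 605 lower genes called under both the deposited and the median-of-ratios scaling, and grey points are all others. The solid line marks equal values and the dotted line the median log2 change of -0.61; Mbp, Kif1c, Lpar1 and Rab13 lie far above both, and Actb lies near the dotted line.

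A list of 11 mRNAs that localize to fibroblast protrusions through the APC protein was fixed beforehand. With the deposited scaling 10 of the 11 rose in OPC protrusions. The same number rose after median-of-ratios scaling, which is no second test, since that scaling raised most log2 changes. The count was also 10 when adjusted over the list alone. Rab13, a small GTPase gene whose mRNA is the best known of them (chromosome 2, 209014516 to 209019148), stood at 122 ± 5.45 FPKM in protrusions and 13.3 ± 0.19 in soma, 9.12-fold higher with an adjusted p of 4.93e-06. Kif1c, Pkp4 and Trak2 were the members with the largest changes, at 11.7-fold, 11.3-fold and 10.9-fold. Net1, a Rho guanine nucleotide exchange factor, was 9.13-fold higher at 46.6 ± 4.42 against 5.11 ± 0.06 FPKM. Inpp1, the remaining member and named after its values were seen, was at 2.49 ± 0.30 and 2.81 ± 0.11 FPKM with an adjusted p of 0.555. The median log2 change of the list was 2.96, and camera placed it above other genes with an adjusted p of 2.84e-23. That call was lost at an adjusted p = 0.198 with an estimated correlation.

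**Figure D2:**
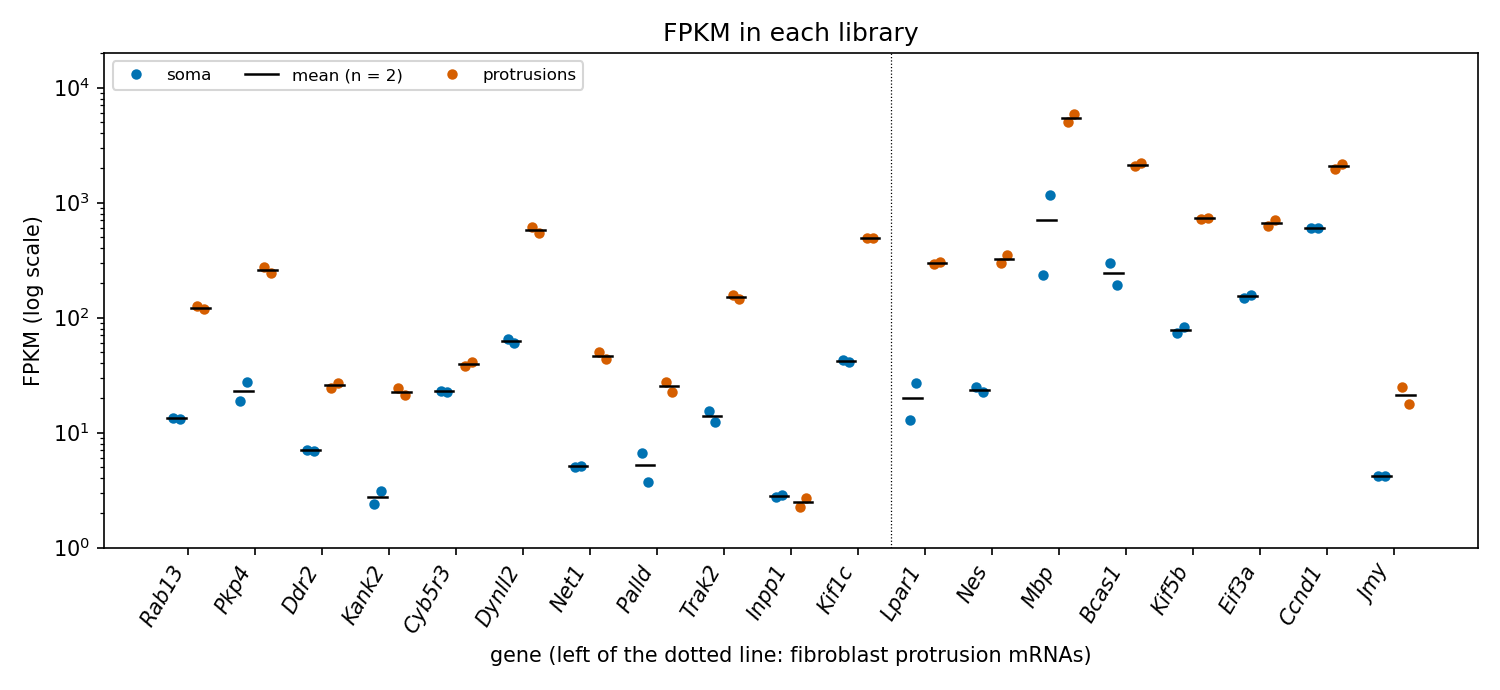
FPKM of single libraries (points, log scale) and their means (black bars, n = 2 per fraction) for the 11 fibroblast protrusion mRNAs, left of the dotted line, and for 8 other genes named in the text. Both protrusion libraries lie above both soma libraries for every gene shown except Inpp1, and soma 2 holds more Mbp (1163 FPKM) than soma 1 (237 FPKM).

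Microtubule and motor genes moved both ways with the deposited scaling. Of 53 microtubule and motor genes, 21 rose and 16 fell, the same numbers when adjusted over the list alone, and after median-of-ratios scaling 29 rose and none fell (1 at an unadjusted p under 0.05). Kif5b, the ubiquitous kinesin-1 heavy chain, was 9.34-fold higher at 731 ± 9.06 against 78.2 ± 5.77 FPKM, and Kif1c and Trak2, also members of the fibroblast list, were the other leading genes. Further risers, picked after their values were seen, were Mtap4 (microtubule-associated protein 4, 7.94-fold), Dync1li2 (a dynein light intermediate chain, 7.27-fold), Kif5a (6.61-fold), Kif5c (6.57-fold) and Map1b (6.49-fold). The neuronal tubulin Tubb3, a member of the neuron list, fell from 57.2 ± 1.46 to 27.3 ± 0.46 FPKM with the deposited scaling, and Tubb5, picked in the same way, from 717 ± 63.5 to 362 ± 3.36 FPKM. Relative to the median gene Tubb3 was at -0.35 after median-of-ratios scaling and no longer passed (adjusted p = 0.136). The list median was 0.01 with the deposited scaling, -0.09 when FPKM were rescaled without ribosomal protein genes and 0.70 after median-of-ratios scaling. Camera placed the list above other genes (adjusted p = 4.54e-13), and the call was lost at an adjusted p = 0.531 with an estimated correlation.

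Myelin transcripts did not move together. Mbp, whose mRNA is known to travel into oligodendrocyte processes, stood at 5449 ± 660 FPKM in protrusions and 700 ± 655 in soma, where soma 1 had 237 and soma 2 had 1163. Bcas1, a marker of newly forming oligodendrocytes, was 8.71-fold higher at 2138 ± 98.4 against 245 ± 74.8 FPKM, with an adjusted p of 3.46e-05. Cldn11, the tight junction protein of myelin, was at 10.5 ± 6.24 against 25.6 ± 2.22 FPKM, a ratio of 0.41, or 0.24 without protrusion 2. Plp1, the main proteolipid of myelin, picked after its values were seen, was at 512 ± 51.5 and 510 ± 395 FPKM (adjusted p = 0.613). Of 23 tested genes of the myelin list 8 rose and 6 fell, as many when adjusted over the list alone, and after median-of-ratios scaling 9 rose and none fell (1 at an unadjusted p under 0.05). Its median was -0.30 and its mean 0.25, the median turned to 0.24 after median-of-ratios scaling, and camera placed the list above other genes (adjusted p = 0.000285, but adjusted p = 0.531 with an estimated correlation). Mbp no longer passed with quantile normalization (log2 change 2.46, adjusted p = 0.0717) or a robust variance prior (adjusted p = 0.0705). The call of Cldn11 ended after median-of-ratios scaling (adjusted p = 0.182), and its log2 change was -0.74 without protrusion 1 against -1.32 with all libraries.

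Of 23 OPC markers none rose with the deposited scaling, also at an unadjusted p under 0.05, and 17 fell, 18 when adjusted over the list alone. After median-of-ratios scaling 2 fell and none rose (1 higher and 4 lower at an unadjusted p under 0.05). Those 2 were the transcription factors Nkx2-2, at 15.6 ± 5.43 against 49.4 ± 7.24 FPKM, and Olig2, at 47.8 ± 8.54 against 140 ± 37.6 FPKM. Sox10 was at 36.3 ± 9.77 against 85.9 ± 19.1 FPKM, the growth factor receptor Pdgfra at 38.0 ± 8.62 against 64.9 ± 24.1 FPKM and the proteoglycan NG2 gene Cspg4 at 4.93 ± 2.10 against 10.2 ± 5.17 FPKM, a ratio of 0.48, or 0.76 without soma 1. These 3 passed with the deposited scaling (adjusted p = 0.00231, 0.0322 and 0.0329) but not after median-of-ratios scaling (0.124, 0.94 and 0.607). Without protrusion 1 their log2 changes were -0.96, -0.50 and -0.51, against -1.23, -0.73 and -0.88 with all libraries. Those of Pdgfra and Cspg4 were -0.35 and -0.39 without soma 1. The list median of -0.88 was not called apart from other genes by camera (adjusted p = 0.169), although it was without soma 2 (adjusted p = 1e-06). Without soma 1 its direction turned (adjusted p = 0.882).

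Most cytosolic ribosomal protein transcripts were higher in protrusions. Of 77 genes 60 rose and none fell, 62 rose when adjusted over the list alone, and 77 rose after median-of-ratios scaling, but 28 after quantile normalization. Rps2 was 3.96-fold higher at 271 ± 123 against 68.4 ± 9.12 FPKM, Rps12 2.48-fold at 455 ± 20.8 against 183 ± 35.8 FPKM and Rplp1 2.46-fold at 2773 ± 306 against 1129 ± 221 FPKM. Near-identical pseudogenes make these values uncertain, and the rDNA-like loci rose in the same libraries, holding 22.1% of the summed FPKM in protrusion 1. For the list, with a median of 0.73, camera gave an adjusted p of 6.62e-44, but an adjusted p = 0.542 with an estimated correlation, and fry did not pass (0.0972, or 0.0653 after median-of-ratios scaling). The log2 change of Rplp1 was 1.42 without protrusion 1 and 1.19 without protrusion 2, against 1.31 with all libraries. With quantile normalization it was 0.47 and Rplp1 no longer passed (adjusted p = 0.0745).

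Among 37 translation factors 6 rose and 11 fell, 5 and 9 when adjusted over the list alone, and 14 rose and none fell after median-of-ratios scaling. Eif3a, the largest subunit of initiation factor eIF3, was 4.36-fold higher at 666 ± 50.01 against 153 ± 6.89 FPKM. Eif5b was 3.37-fold higher at 139 ± 4.99 against 41.2 ± 2.81 FPKM and the poly(A)-binding protein gene Pabpc1 2.92-fold higher at 2067 ± 9.53 against 708 ± 68.5 FPKM. Their median was -0.23, above that of all genes, and turned to 0.48 after median-of-ratios scaling. Camera placed the list above other genes (adjusted p = 0.00421), with an adjusted p = 0.834 with an estimated correlation, and the direction turned after quantile normalization (adjusted p = 0.295).

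Of 75 nuclear genes of oxidative phosphorylation 9 rose and 7 fell, none in either direction when adjusted over the list alone (10 and 11 at an unadjusted p under 0.05), and 50 rose and none fell after median-of-ratios scaling. Atp5e, a subunit of ATP synthase, was at 183 ± 5.53 against 103 ± 22.9 FPKM, and Uqcr10, a subunit of complex III, at 29.5 ± 3.30 against 16.1 ± 3.03 FPKM. Ndufs1, a large complex I subunit, was at 21.0 ± 2.83 against 38.6 ± 0.43 FPKM. Without protrusion 1 the log2 changes of Atp5e, Uqcr10 and Ndufs1 were 0.81, 0.73 and -0.72, against 0.85, 0.84 and -0.85 with all libraries. The call of Ndufs1 was lost after median-of-ratios scaling (adjusted p = 0.356). Those of Atp5e and Uqcr10 were lost when the trend with exon length was removed (0.0989 and 0.0796). The median of these genes was 0.16, against -0.61 for all genes. Camera gave an adjusted p of 9.27e-11, which became an adjusted p = 0.834 with an estimated correlation.

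Most actin genes did not pass with the deposited scaling, and a few rose strongly. Jmy, a nucleation promoting factor of actin (chromosome 2, 42238034 to 42292484), was 5.09-fold higher at 21.3 ± 4.97 against 4.18 ± 0.002 FPKM, with a log2 change of 2.09 (SE 0.21) and an adjusted p of 0.000117. Wasf3, a member of the WAVE family that activates Arp2/3, was 7.39-fold higher at 120 ± 0.97 against 16.2 ± 4.42 FPKM. Actb was at 1940 ± 237 against 3167 ± 51.0 FPKM, a fall of 0.71 on the log2 scale (adjusted p = 0.0462), and after median-of-ratios scaling its change was -0.003 (adjusted p = 0.993). With the deposited scaling its log2 change was -0.59 without protrusion 1 and -0.84 without protrusion 2. Of 59 actin genes 4 rose and 20 fell, 3 and 18 when adjusted over the list alone, while 17 rose and none fell after median-of-ratios scaling (1 at an unadjusted p under 0.05). Their median was -0.43 and turned to 0.26 after that scaling. Camera gave no call (adjusted p = 0.119), but called the list higher without protrusion 1 (0.0455) and after median-of-ratios scaling (0.00179).

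Of 40 Rho GTPases and regulators 6 rose and 17 fell, as many when adjusted over the list alone, and 11 rose and 2 fell after median-of-ratios scaling. Net1 led the rises, and Rhob fell from 189 ± 13.0 to 60.6 ± 5.98 FPKM under both scalings. A list median of -0.50 turned to 0.16 after median-of-ratios scaling, and camera gave an adjusted p of 0.154, or 0.0395 without soma 1. Of 43 RNA granule and RNA transport genes 2 rose and 24 fell, as many when adjusted over the list alone, and 7 rose and 5 fell after median-of-ratios scaling. The stress granule genes Tia1 (5.10 ± 1.07 against 17.3 ± 1.27 FPKM) and Tial1 (21.5 ± 4.68 against 57.2 ± 2.64 FPKM) and the splicing regulator Mbnl2 (5.92 ± 0.29 against 17.0 ± 2.08 FPKM) fell under both scalings. Their list median of -0.52 turned to 0.11 after median-of-ratios scaling, and camera gave an adjusted p of 0.401. With the deposited scaling 6817 of all 11812 tested genes fell, with a median of -0.61, so by its median neither list fell more than the typical gene.

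Transcripts of the guidance and growth factor receptor list, which also holds guidance ligands, and of the matrix and adhesion list were mostly lower with the deposited scaling. So were 6817 of all 11812 tested genes. The medians of the guidance and the matrix lists were -0.73 and -0.58, against -0.61 for all genes. The matrix list thus fell no more than the typical gene. Of 37 guidance and growth factor receptor genes, ligands among them, 1 rose and 25 fell, as many when adjusted over the list alone. After median-of-ratios scaling 1 rose and 3 fell. The riser was Ephb1, an ephrin receptor, 3.10-fold higher at 18.2 ± 3.92 against 5.86 ± 0.88 FPKM. Sema3a, a secreted semaphorin, fell from 70.1 ± 1.06 to 26.6 ± 5.76 FPKM and Sema4d from 10.6 ± 2.87 to 3.18 ± 0.34 FPKM. Of 38 matrix and adhesion genes 1 rose and 20 fell, 1 and 19 when adjusted over the list alone, and 5 rose and 3 fell after median-of-ratios scaling. Dag1, which encodes the laminin receptor dystroglycan, fell from 47.8 ± 2.69 to 16.0 ± 2.04 FPKM. Camera called neither list apart from other genes (adjusted p = 0.277 and 0.54), although the guidance list was called lower without soma 2 (0.0234).

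Nearly all cholesterol synthesis genes were lower with the deposited scaling. Of 23 genes 22 fell with the deposited scaling, 23 when adjusted over the list alone, and 10 after median-of-ratios scaling, and none rose. Dhcr7, the last enzyme of the pathway, was at 7.03 ± 0.05 FPKM in protrusions against 30.7 ± 4.72 in soma (adjusted p = 0.00011). Msmo1 was at 45.6 ± 4.07 against 179 ± 2.27 FPKM, and the low density lipoprotein receptor gene Ldlr at 15.4 ± 2.64 against 50.6 ± 4.61 FPKM. The list median was -1.29, and -0.63 after median-of-ratios scaling. Camera placed the list below other genes (adjusted p = 2.04e-05, but adjusted p = 0.834 with an estimated correlation), and fry did not pass (0.0749, or 0.161 after median-of-ratios scaling).

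Of 34 immediate early and stress genes 25 fell and none rose, 26 fell when adjusted over the list alone, and 10 fell after median-of-ratios scaling. Egr1, an immediate early transcription factor, was at 14.6 ± 4.12 against 52.1 ± 4.54 FPKM and Klf6 at 5.77 ± 1.80 against 20.9 ± 3.90 FPKM. Camera placed the list below other genes with an adjusted p of 0.00421, or an adjusted p = 0.834 with an estimated correlation. Of 42 cell cycle genes 36 fell and 1 rose, 37 and 1 when adjusted over the list alone, but 1 fell and 1 rose after median-of-ratios scaling. The riser was Ccnd1, the G1 cyclin D1, 3.41-fold higher at 2064 ± 139 against 605 ± 3.03 FPKM. The mitotic cyclin Ccnb1 was at 5.60 ± 0.66 against 23.2 ± 10.8 FPKM, with 30.8 in soma 1 and 15.6 in soma 2, and its call was lost after median-of-ratios scaling (adjusted p = 0.0586). Camera placed the cell cycle list below other genes with an adjusted p of 0.01, or an adjusted p = 0.834 with an estimated correlation, and the call was also lost without soma 1 (0.591) and without protrusion 2 (0.127).

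ER translocation and folding genes (45 tested) had 33 lower and 1 higher, as many when adjusted over the list alone, and 5 lower and 10 higher after median-of-ratios scaling. Hspa5, the ER chaperone BiP, was at 81.2 ± 23.7 against 215 ± 46.5 FPKM, and after median-of-ratios scaling it did not pass (adjusted p = 0.0623). Spliceosome genes (46 tested) had 33 lower and none higher, as many when adjusted over the list alone, and 6 lower and 7 higher after median-of-ratios scaling. Sf3a2 fell from 57.4 ± 2.44 to 20.3 ± 4.43 FPKM and Srsf5 from 213 ± 3.34 to 85.0 ± 8.81 FPKM under both scalings. Proteasome genes (31 tested) had 23 lower and none higher, as many when adjusted over the list alone, and none in either direction after median-of-ratios scaling (3 higher and none lower at an unadjusted p under 0.05). Psmc6, an ATPase of the proteasome cap, was at 23.3 ± 1.18 against 46.9 ± 5.85 FPKM, and after median-of-ratios scaling it did not pass (adjusted p = 0.193). With the deposited scaling the medians of the ER, spliceosome and proteasome lists were -0.91, -0.71 and -0.62, against -0.61 for all genes. Camera called none of the 3 lists apart from other genes (adjusted p = 0.164, 0.102 and 0.154), although the ER list was called lower without soma 1 (0.0395). After quantile normalization the ER, spliceosome and proteasome lists were called lower (adjusted p = 0.000407, 4.45e-05 and 2.4e-07), and so was the spliceosome list when the trend with exon length was removed (0.0214). With the replicate number as a block, which is not stated to pair the libraries, camera called the spliceosome (0.0387) and proteasome (0.0351) lists lower.

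**Figure D3:**
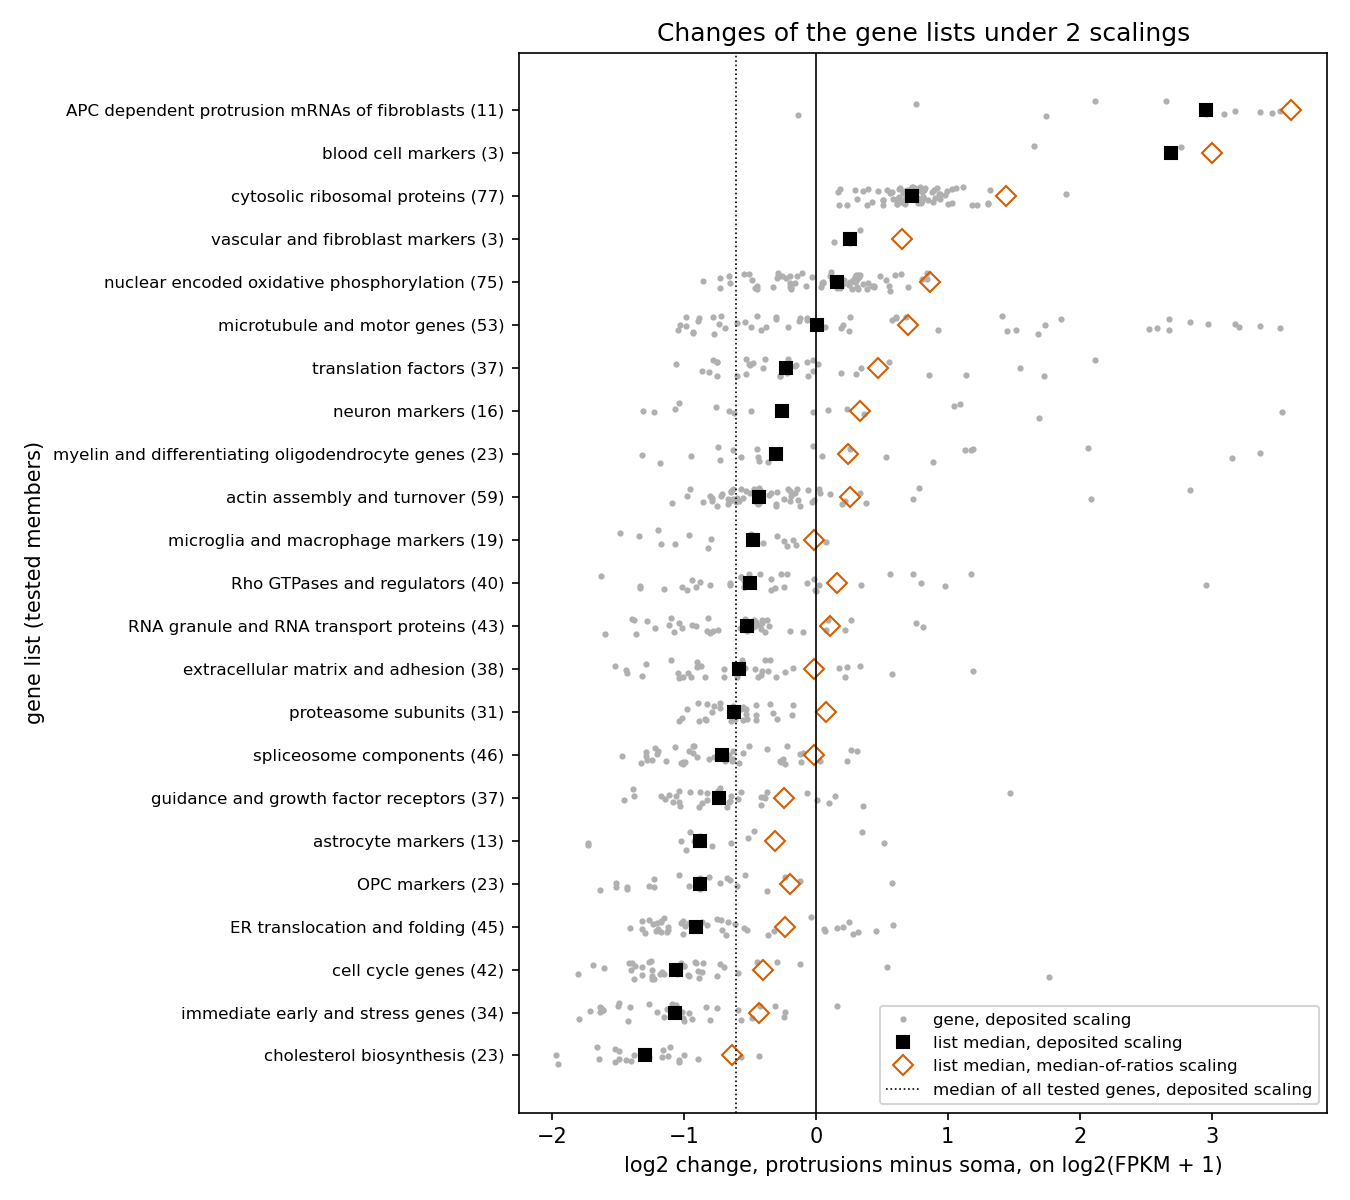
Log2 change of protrusions minus soma on log2(FPKM + 1) for each tested member (grey points) of the 23 lists with at least 3 tested members, with list medians under the deposited (black squares) and the median-of-ratios scaling (orange diamonds). The dotted line marks the median of all tested genes, -0.61. The fibroblast protrusion mRNAs lie highest and cholesterol genes lowest. After median-of-ratios scaling, which raised most log2 changes, the medians of the myelin, actin, neuron, Rho, translation, RNA granule and proteasome lists turn positive.

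Markers of other cell types were measured in the same libraries. Of 13 astrocyte markers 1 rose and 9 fell, as many when adjusted over the list alone, and after median-of-ratios scaling 1 rose and 2 fell, Sox9 (8.08 ± 0.49 against 29.1 ± 2.49 FPKM) and Id3 (6.34 ± 1.26 against 23.2 ± 3.28 FPKM). Gfap was at 2.55 ± 1.63 and 1.83 ± 1.45 FPKM (adjusted p = 0.405). Its log2 change was 0.35 with all libraries and 0.90 without soma 1, and it turned to -0.20 without soma 2 and -0.14 without protrusion 1. Of 19 microglia and macrophage markers none rose and 6 fell, as many when adjusted over the list alone, and none moved after median-of-ratios scaling (3 lower at an unadjusted p under 0.05). The microglial receptor gene Csf1r was at 4.28 ± 2.03 against 13.3 ± 1.67 FPKM, a ratio of 0.32, or 0.21 without protrusion 2. Camera called neither list (adjusted p = 0.54 and 0.926), although the astrocyte list was called lower without soma 2 (0.00636) and the microglial list lower without protrusion 2 (0.0369).

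Of 16 neuron markers 4 rose and 7 fell, as many when adjusted over the list alone, and 4 rose and none fell after median-of-ratios scaling. The risers included the neurofilament genes Nefm, at 138 ± 38.3 against 12.1 ± 8.01 FPKM, and Nefl, at 15.4 ± 3.45 against 4.52 ± 3.26 FPKM, while the synaptic gene Snap25 was at 6.17 ± 1.95 against 17.3 ± 7.95 FPKM. The rise of Nefl was 2.26-fold without soma 1 and 6.94-fold without soma 2. The call of Snap25 was lost after median-of-ratios scaling (adjusted p = 0.166), and its log2 change was -1.03 without protrusion 1 against -1.31 with all libraries. Their median was -0.26 and their mean 0.06, and the median turned to 0.34 after median-of-ratios scaling. Camera placed the list above other genes at an adjusted p of 0.026, lost at an adjusted p = 0.531 with an estimated correlation and at 0.0941 without protrusion 1. It was also lost after median-of-ratios scaling (0.254), with quantile normalization (0.137) and at a mean of at least 5 FPKM (0.0518).

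Only 3 of 16 matched vascular and fibroblast markers were expressed enough to test, all with means below 3 FPKM in both fractions, and none passed the limma test, also when adjusted over the list alone or at an unadjusted p under 0.05 with the deposited scaling. None passed after median-of-ratios scaling (2 higher at an unadjusted p under 0.05). Fn1 was at 2.60 ± 1.28 and 1.82 ± 0.79 FPKM and Col1a1 at 1.52 ± 0.51 and 1.10 ± 0.31 FPKM. The log2 change of Fn1 was 0.34 with all libraries and 0.63 without soma 1, and without protrusion 1 it turned to -0.032. The list stood above other genes in camera (adjusted p = 0.0373), a call lost at an adjusted p = 0.834 with an estimated correlation, without soma 2 (0.265) and without protrusion 1 (0.2), after median-of-ratios scaling (0.178) and with quantile normalization (0.0854). The 3 tested blood cell markers, all haemoglobin genes, rose under both scalings and when adjusted over the list alone. Hba-a2 had 0 and 3 recovered reads in the soma libraries and 183 and 241 in the protrusion libraries, a rate ratio of 187 (95% exact interval 63.4 to 909). Hba2 had 2 and 0 against 164 and 219 reads, a ratio of 253 (69.5 to 2096), and Hbb had none in soma and 68 and 101 in protrusions, at least 74.4-fold higher against a floor of 3 reads over both soma libraries. These genes share sequence, so reads of one may be counted in another. Camera placed the list above other genes (adjusted p = 6.8e-09, but adjusted p = 0.296 with an estimated correlation). The 3 genes passed the filter only through the protrusion libraries, so this call adds no support for a rise of blood cell markers. All 12 matched mitochondrially encoded genes were listed at 0 in every library, and of the nuclear noncoding RNAs 1 was matched and it was too low to test.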

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

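The alternatives of voom, exon length, rDNA-like loci, summed FPKM and fry after rescaling were chosen after seeing the data. Of the named genes' values, 1500 kept direction and side of the threshold, 105 no longer passed, 2 newly passed and 3 turned. Counts of higher and lower genes were 1922 and 605 with median-of-ratios scaling, 1284 and 990 with quantile normalization and 224 and 304 against a 1.5-fold minimum change. They ran from 406 to 955 and from 1761 to 6622 with a library left out, and kept within 1.5 times of 854 and 6817 otherwise. Replicate numbers are not stated to pair the libraries. With the replicate block the counts were 1016 and 7527, the replicate differences of the fractions correlated at 0.35 across genes, and the spliceosome (adjusted p 0.0387) and proteasome (0.0351) lists were called lower. Of the 12 list calls none held with an estimated correlation: adjusted p was 0.198 for fibroblast protrusion mRNAs, 0.296 for blood, 0.531 for myelin, neuron and motor genes, 0.542 for ribosomal proteins and 0.834 for vascular, translation, oxidative phosphorylation, cell cycle, immediate early and cholesterol genes. Fry, which tests against 0, called 2 lists, or 4 after median-of-ratios scaling. Its adjusted p was 0.634 (myelin), 0.58 (vascular), 0.0972 (ribosomal proteins, immediate early), 0.682 (oxidative phosphorylation), 0.084 (motor), 0.143 (cell cycle) and 0.0749 (cholesterol), with the direction turned for neuron (0.0972), translation (0.754), actin (0.172) and Rho genes (0.108). After median-of-ratios scaling fry gave 0.0963 (myelin), 0.187 (neuron), 0.352 (vascular), 0.0653 (ribosomal proteins), 0.108 (translation), 0.0812 (oxidative phosphorylation), 0.038 (actin), 0.764 (cell cycle), 0.216 (immediate early) and 0.161 (cholesterol), with RNA granule (0.485) and proteasome genes (0.607) turned. Camera after that scaling gave 0.254 (neuron), 0.178 (vascular) and 0.00179 (actin), with RNA granule (0.851) and proteasome genes (0.635) turned. Quantile normalization gave 0.137 (neuron), 0.0854 (vascular), 0.000407 (ER), 4.45e-05 (spliceosome) and 2.4e-07 (proteasome), with translation (0.295) and actin genes (0.595) turned. At a mean of at least 5 FPKM neuron genes gave 0.0518, and without the exon length trend the spliceosome list gave 0.0214 and the microglial list turned (0.942). With a library left out, adjusted p ran from 1e-06 to 0.882 (OPC markers), 0.00636 to 0.882 (astrocyte), 0.0369 to 0.876 (microglia), 0.00705 to 0.0941 (neuron), 0.00557 to 0.265 (vascular), 0.0455 to 0.14 (actin), 0.0395 to 0.557 (Rho), 0.0234 to 0.56 (guidance), 0.0395 to 0.365 (ER) and 2.63e-10 to 0.591 (cell cycle), and OPC, astrocyte and microglial markers turned in 1 of these each. The log2 change ran from -0.032 to 0.71 for Fn1 and from -0.20 to 0.90 for Gfap. The cause was not tested for these changes, except that fry compares with 0 and not with the other genes. Camera with an estimated correlation also rests on 2 residual degrees of freedom, so a call lost there need not mean correlated genes. Depth limits few of the tested genes, since 125 of them had fewer than 50 recovered reads on average.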

Other observations

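Among the tests below, those of the 4 rescalings (2 of them planned as alternatives), that of summed marker levels and that of the soma libraries were chosen only after the result was seen.

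Far more genes were lower than higher in protrusions with the deposited scaling. The pair of libraries closest in depth, soma 2 and protrusion 2, whose totals differ 1.08-fold, still had a median log2 change of -0.52, which argues against depth as the cause. After median-of-ratios scaling 23.9% of the calls were lower, neither near an even split nor above 75%, and that scaling centres the data by construction. With all genes scaled to summed FPKM 92.0% of the calls were lower (median -0.749), and leaving the 7 loci called rDNA-like or the ribosomal protein genes out of that sum gave 87.8% (-0.588) and 90.8% (-0.684), which argues against displacement by either group alone as the whole cause. A true fall of most transcripts per protrusion and displacement by a wider set of abundant transcripts cannot be told apart from these relative values.

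The fibroblast protrusion mRNAs were high in OPC protrusions. Removing the trend with exon length left 102% of their median log2 change, which argues against a length bias. RNA of fibroblasts or vascular cells in the protrusion fraction is also argued against as the main source, though only by marker sums whose bound was set afterwards. The 3 markers tested lay 0.86 above the median of all genes, between the bounds set beforehand, which decides nothing. The summed level of the 16 matched markers, collagens and fibronectin among them, went from 6.34 to 8.10 FPKM, a rise of 0.113% of that of the fibroblast protrusion mRNAs (201 to 1768 FPKM). The series held no fibroblast sample to show how the levels of these markers and mRNAs compare in such cells or in their extensions. Transport of these mRNAs into OPC protrusions by the route known from fibroblasts is a candidate explanation that was not tested.

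Mbp was high in protrusions. Its log2 change lay 3.70 above the median of the 22 other tested myelin genes, more than their SD of 1.11, which argues against an equal rise of all myelin genes. That gap does not exclude more mature cells in the protrusion fraction, because genes of different stages need not rise alike. Of the 22, 5 also had a log2 change above 1. The soma libraries differ 4.91-fold in Mbp, yet without soma 1 the change was still 2.22 and without soma 2 it was 4.51, which argues against that difference as the cause. Localization of Mbp mRNA to protrusions may account for the pattern and was not tested beyond these values.

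The reads of the haemoglobin genes Hba-a2, Hba2 and Hbb, near 0 in soma and at 68 to 241 per gene in protrusions, are given as values, and Hbb-b1 had none in soma and 6 and 7 in protrusions. Alas2, the erythroid enzyme of haem synthesis, had no reads in soma and 2 and 6 in protrusions, and Slc4a1, the red cell anion exchanger, had 9 and 9 in soma and 1 and 16 in protrusions.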
